A study of Homo sapiens with 28 samples.

How the data were processed

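RNA sequencing libraries of MCF-7 cells transfected with siLuc or siAGO1 (2 each) and ChIP-seq libraries of MCF-7 and MCF10A cells (1 per target and line) were analysed from processed files. Per the labels' protocols, cells for ChIP were plated for 72 h and fixed with 1% formaldehyde. Samples were grouped by their titles. Files of 11 of the 28 samples were used. Total histone H3, H3K9me2, H3K36me3, H3K27me3, 5metC in MCF-7, the Millipore AGO1 antibody in MCF10A, the controls without antibody and reads over exon junctions were not analysed here, so splicing itself was not measured.

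The RNA files hold read counts per gene, deposited by the authors as whole numbers over merged exons with genes without reads left out, per the labels and the file names, which name Ensembl release 54; a gene missing from a library was set to 0. The RPKM values beside them were computed by the authors from the same counts, per the labels, and were used only in an alternative. The authors' deposited table of changed genes gives a log2 fold change and a p-value per gene, per the file headers; its test, and whether the p-values were adjusted, is not given in the sources used here, and all its p-values lie under 0.05. The ChIP files hold signal, deposited by the authors as the coverage by overlapping reads inside the regions they kept, per the file headers; values are whole numbers except for the Millipore antibody, whose signal is in scaled steps. The aligner, the region caller, its threshold and the genome build are not given in the sources used here. Positions were compared with a gene table of GRCh38 only to see that the build differs; none of its coordinates are given here, and it served otherwise only for names and for which genes neighbour each other. Of 20972 gene identifiers, 16908 took a symbol from the table of gene names and 70 more from the authors' deposited table.

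Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr left 15202 genes, libraries were scaled by TMM, and siAGO1 was compared with siLuc by glmQLFit and glmQLFTest without a block, at a Benjamini-Hochberg adjusted p under 0.05. The median log2 fold change of all tested genes was 0.00. SE is the log2 fold change over the square root of the F statistic. CPM values are TMM-scaled. The biological coefficient of variation was 16.1%, and totals ran from 18512828 to 30891347 counts. On simulated counts for this comparison with 200 changed genes, 66% of the genes changed by a log2 of 1 and 95% of those changed by a log2 of 2 were recovered, with 10 false calls over 14995 genes. Far more genes were called in the data, so these shares do not measure how complete those calls are. Each simulated gene took its spread from the trend over all genes, so genes with a wider spread of their own were not simulated. Named genes followed a rule fixed before the data were examined: AGO1 to AGO4, the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups, and up to 3 members per gene list with the smallest adjusted p. For some lists fewer are printed. STAT1, MDM2, ESR1, CBX5, NELFCD, CD44, SFN, ACTA2, CAV2, and C3orf14, PPA1 and ECT2 from the authors' deposited table were chosen after their values were seen.

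The 32 gene lists, also fixed before the data were examined, were Argonaute and microRNA machinery, SR and hnRNP splicing regulators, core spliceosome, heterochromatin and DNA methylation, Pol II elongation and cohesin, estrogen response, luminal, basal, mesenchymal, leukocyte and endothelial markers, p53 targets, G2 and mitosis, G1/S and DNA replication, replication-dependent histones, interferon response, NF-kB and inflammatory response, cholesterol synthesis, fatty acid synthesis, unfolded protein response, ATF4 and amino acid response, hypoxia and glycolysis, heat shock, immediate early genes, apoptosis regulators, TGF-beta response, let-7 targets, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation, abundant small and structural RNAs, and epithelial junctions. They were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and again with an estimated one, adjusted over the lists. With an estimated correlation camera uses only the residual degrees of freedom of the RNA libraries, which are few. A call lost there does not by itself show correlation between genes. Of the 10 abundant small and structural RNAs, 0 passed the filter on low counts, so that list was not tested.

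Touching or overlapping intervals of a ChIP file were merged into regions with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and a region's height is the highest authors' value in it. Overlap of at least 1 bp was compared with 100 circular shifts within chromosomes; an overlap is described as above or below when it lay outside all 100. Shifts of 20 to 200 kb were added after seeing the data, as was leaving out chromosomes 17 and 20. Wilson intervals at 95% came from scipy 1.17.1 for regions and from the formula in R for shares of counts, and cover counting error only, since neighbouring regions and reads are not independent. The overlap count was tested on simulated regions. Figures were drawn with matplotlib 3.10.9.

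Alternatives were DESeq2 1.42.0, RLE size factors, library totals, no filter, a CPM of at least 1 in 2 libraries, the replicate number as a block, each library left out, limma on log2(RPKM + 0.1) and log2(RPKM + 1), and a minimum log2 fold change of 1. For regions they were overlap of at least 50% of the shorter region, a distance of 1 kb, the higher-scoring part of each set, equal numbers of regions, and random placement on regions of the other sets. A fit that leaves out a library assumes that the lone library of an arm varies like the other group.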

Results

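Argonaute-1 (AGO1), a small-RNA-binding protein of the RNA interference machinery, was profiled in human breast cell lines by chromatin immunoprecipitation with sequencing (ChIP-seq), and its transcript was depleted by small interfering RNA (siRNA) before RNA sequencing. The lines were MCF-7, an estrogen receptor-positive breast cancer line, and MCF10A, a non-tumorigenic mammary epithelial line. Of the 28 samples in the series, 24 were ChIP-seq samples and 4 were RNA libraries of MCF-7, and files of 11 samples were analysed here. The RNA libraries comprised 2 controls transfected with an siRNA against luciferase (siLuc) and 2 transfected with an siRNA against AGO1 (siAGO1), each at 20 nM for 72 h. Their totals were 21899067 and 28235383 counts for siLuc replicates 1 and 2, and 30891347 and 18512828 counts for siAGO1 replicates 1 and 2. Differences between replicates exceeded sampling noise, with a chi-square per degree of freedom of 15.4 between the siLuc libraries and 21.4 between the siAGO1 libraries. The ChIP-seq files covered AGO1 with 2 antibodies in MCF-7 (the Millipore antibody and clone 4B8), AGO1 with 4B8 in MCF10A, the heterochromatin protein HP1 alpha in both lines, and RNA polymerase II (RNAPII) and methylated cytosine (5metC) in MCF10A. Each target was represented by 1 library per line, so region comparisons carry no replicate error and no p-value.

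To check the knockdown, Argonaute transcripts were compared first. AGO1 (ENSG00000092847) fell from 71.2 ± 6.24 CPM (normalised read counts scaled to library size) in siLuc to 13.8 ± 0.521 CPM in siAGO1 (mean ± SD, n = 2 each), a log2 fold change of -2.36 ± 0.118 (SE; adjusted p = 0.00172, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The siLuc libraries held 66.8 and 75.6 CPM and the siAGO1 libraries 14.2 and 13.5 CPM. None of the paralogs passed the same edgeR test: AGO2 had a log2 fold change of -0.24 (adjusted p = 0.201), AGO3 one of -0.92 (adjusted p = 0.0763) and AGO4 one of 0.22 (adjusted p = 0.377). AGO3 was measured at 2.28 ± 0.104 CPM in siLuc, the lowest of the 4 genes.

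**Figure D1:**
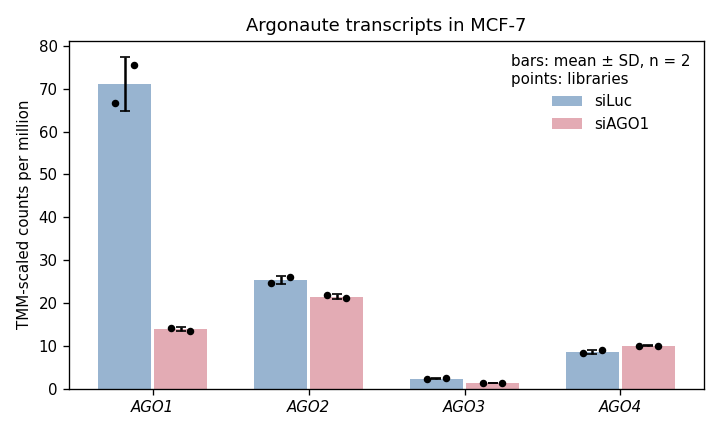
TMM-scaled CPM (y axis) of AGO1 to AGO4 in siLuc and siAGO1 libraries; bars are means with SD (n = 2) and points are libraries. AGO1 drops from 71.2 to 13.8 CPM, while AGO2, AGO3 and AGO4 did not pass the test.

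To examine which transcripts changed after AGO1 depletion, all expressed genes were tested between siAGO1 and siLuc. Among genes that passed the test and averaged at least 5 CPM, the largest rises were FOXI1, a forkhead transcription factor, at a log2 fold change of 4.73 ± 0.286 (SE), FSTL4 at 3.02 ± 0.165, TAGLN, which encodes the actin-binding protein transgelin, at 3.0 ± 0.107, and BIRC3, an inhibitor of apoptosis, at 2.95 ± 0.469. NT5E, the ecto-nucleotidase CD73, rose by 2.91 ± 0.196, PSCA by 2.69 ± 0.110 and the extracellular matrix gene TGFBI by 2.50 ± 0.209. STON1-GTF2A1L, at 2.45 ± 0.229, is a read-through gene overlapping its neighbours, so its reads cannot be assigned to it with certainty. FOXI1 went from 0.549 ± 0.180 to 14.5 ± 1.53 CPM and TAGLN from 16.4 ± 0.0694 to 131 ± 12.3 CPM (mean ± SD, n = 2 each). The largest falls among such genes were TP63, the transcription factor p63 of basal epithelia, at -2.47 ± 0.227, AGO1 itself, and IGFBP3, an insulin-like growth factor binding protein, at -2.34 ± 0.166. They were followed by TMX1 at -2.23 ± 0.539, the mitotic kinesin KIF14 at -2.10 ± 0.231, HMMR, a hyaluronan receptor also found on the spindle, at -2.01 ± 0.216, SYTL4 at -1.99 ± 0.157 and SLITRK6 at -1.98 ± 0.143. TP63 went from 14.8 ± 1.47 to 2.63 ± 0.590 CPM and SLITRK6 from 105 ± 12.8 to 26.6 ± 3.81 CPM.

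In all, 3468 of 15202 genes tested had an adjusted p under 0.05 by edgeR's quasi-likelihood test, of which 1637 were higher and 1831 lower in siAGO1. Of these, 616 were higher and 486 lower by a log2 fold change of at least 1. Leaving out siLuc replicate 1 reduced the count to 1723, and leaving out siLuc replicate 2 reduced it to 1601, with fewer samples in the fit. The size of the fall of TMX1 (edgeR adjusted p = 0.0333) depended on siLuc replicate 1. Its siLuc level was 18.0 ± 12.5 CPM, and its log2 fold change was -1.29 without siLuc replicate 1, against -2.23 with all libraries. It was -2.67 without siAGO1 replicate 1 and -1.93 without siAGO1 replicate 2. The labels do not state that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

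**Figure D2:**
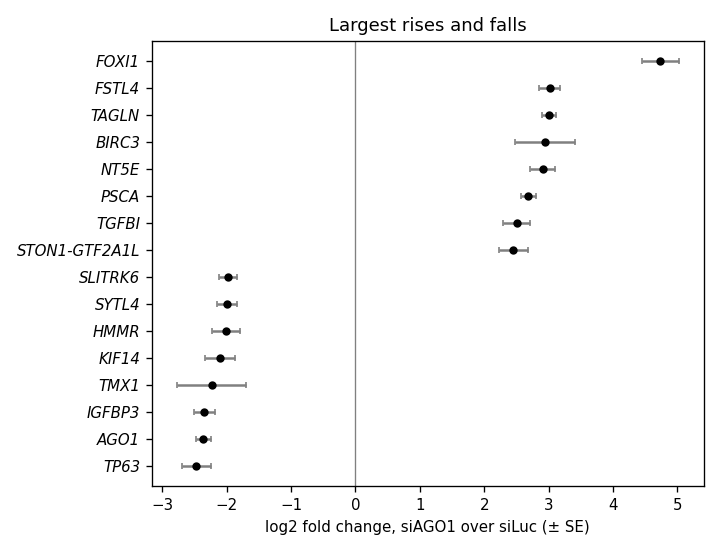
Log2 fold change (siAGO1 over siLuc, x axis) with SE of the 8 largest rises and the 8 largest falls among genes that passed the test and averaged at least 5 CPM. FOXI1 stands farthest right at 4.73, and TP63 farthest left at -2.47; TMX1 has the widest error among the falls.

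Gene lists fixed before the data were examined were then compared. Cell-cycle genes were lower in siAGO1. Of 29 tested genes of G2 phase and mitosis, 25 fell and none rose (26 fell adjusted over the list alone), with a median log2 fold change of -1.60. They included MKI67, the proliferation antigen Ki-67, from 894 ± 97.9 to 236 ± 13.1 CPM (log2 fold change -1.93 ± 0.105), the mitotic kinase PLK1 (-1.62 ± 0.0970) and the kinetochore protein CENPF (-1.62 ± 0.0989). Camera with a preset correlation gave an adjusted p of 5.64e-16 for this list, and adjusted p = 0.357 with an estimated correlation. Of 28 tested genes of the G1/S transition and DNA replication, 23 fell and none rose (24 fell adjusted over the list alone), with a median of -0.90. Thymidine kinase TK1 fell by 1.34 on the log2 scale, from 238 ± 2.57 to 93.7 ± 1.58 CPM, the ribonucleotide reductase subunit RRM2 by 1.29 and the flap endonuclease FEN1 by 1.11. The camera adjusted p was 2.32e-13, and adjusted p = 0.330 with an estimated correlation.

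Targets of the tumour suppressor p53 were higher in siAGO1: 15 of 25 tested rose and none fell (16 rose adjusted over the list alone), with a median log2 fold change of 0.60. The cyclin-dependent kinase inhibitor CDKN1A rose from 801 ± 9.30 to 1956 ± 104 CPM (1.29 ± 0.0777), the antiproliferative gene BTG2 rose by 1.68 ± 0.0848 and the stress cytokine GDF15 by 1.62 ± 0.109. MDM2, another p53 target, was at 0.00 (adjusted p = 1.00 by edgeR). For the p53 list camera gave an adjusted p of 1.11e-08, and adjusted p = 0.330 with an estimated correlation. The number that rose was 9 without siLuc replicate 1 and 9 without siLuc replicate 2.

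Antiviral and inflammatory genes were higher as well. Of 34 tested interferon-response genes, 23 rose and none fell (25 rose adjusted over the list alone), with a median log2 fold change of 0.85; in the same genes siLuc replicate 1 stood above siLuc replicate 2 by a median of 0.52. STAT2 rose from 83.1 ± 0.268 to 139 ± 0.126 CPM (0.75 ± 0.0769), IRF9, its partner in the transcription factor complex downstream of type I interferon, by 0.67 ± 0.0772, and IFI44L from 2.40 ± 0.559 to 9.47 ± 0.117 CPM. STAT1 had a log2 fold change of -0.31 and did not pass (edgeR adjusted p = 0.504), with siLuc replicates 1 and 2 at 450 and 239 CPM. The value was 0.20 without siLuc replicate 1. Without a filter on low counts it was -0.32 and passed (edgeR adjusted p = 0.0288), the 1 interferon gene to fall there. The log2 fold change hardly moved, so that call rests on a different estimate of the spread. For the interferon list camera gave an adjusted p of 1.17e-11, and adjusted p = 0.511 with an estimated correlation. Of 12 tested genes of the NF-kB and inflammatory response, 9 rose and none fell (10 rose adjusted over the list alone), with a median of 1.40. The NF-kB inhibitor NFKBIA rose from 86.5 ± 7.74 to 204 ± 12.2 CPM (1.24 ± 0.0991), the ubiquitin-editing enzyme TNFAIP3 by 1.89 ± 0.198 and the cytokine TNF by 1.73 ± 0.238. Camera gave an adjusted p of 4.15e-05, and adjusted p = 0.508 with an estimated correlation.

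Mitochondrially encoded transcripts took a larger share of the counts in siAGO1. The share was 6.98% (95% Wilson interval 6.97 to 6.99) and 7.70% (7.69 to 7.71) in siLuc replicates 1 and 2, and 11.2% (11.2 to 11.2) and 11.4% (11.4 to 11.4) in siAGO1 replicates 1 and 2; the intervals cover counting error only. Of 13 tested genes 12 rose and none fell (12 adjusted over the list alone), with a median log2 fold change of 0.62; limma on log2 RPKM called 6 with a pseudocount of 0.1 and 5 with 1. MT-CO1 rose from 5085 ± 132 to 10510 ± 1418 CPM (1.05 ± 0.108), MT-ND1 by 0.86 ± 0.0894 and MT-ND6 by 0.86 ± 0.0883; nuclear copies of mitochondrial genes could share reads with them. Camera gave an adjusted p of 5.87e-08, and adjusted p = 0.357 with an estimated correlation.

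Hypoxia and glycolysis, fatty acid synthesis and estrogen-response lists were lower. Of 22 tested hypoxia and glycolysis genes 10 fell and none rose (12 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.66. Lactate dehydrogenase LDHA fell from 555 ± 24.2 to 243 ± 27.6 CPM (-1.19 ± 0.102), the glycolytic enzyme TPI1 by 0.76 and the glucose transporter SLC2A1 by 0.84 on the log2 scale. The hypoxia and glycolysis list had a camera adjusted p of 0.000107, and adjusted p = 0.357 with an estimated correlation. Among 10 tested genes of fatty acid synthesis 4 fell and none rose (6 fell and 1 rose adjusted over the list alone), with ATP citrate lyase ACLY at -1.23 ± 0.0896, the desaturase FADS1 at -0.77 ± 0.0885 and SCD at -0.53 ± 0.0830; camera gave an adjusted p of 0.0125, and adjusted p = 0.508 with an estimated correlation. Of 30 estrogen-response genes 12 fell and 4 rose (14 and 5 adjusted over the list alone), with a median of -0.23. The lysosomal protease CTSD fell from 3342 ± 7.25 to 1528 ± 93.1 CPM (-1.13 ± 0.0789) and SERPINA1 by 1.59 on the log2 scale, while KRT13 rose by 1.37 ± 0.111. The estrogen receptor gene ESR1 was at -0.30 (edgeR adjusted p = 0.0313), a call lost without siLuc replicate 1 (adjusted p = 0.121), without siLuc replicate 2 (0.199) and without siAGO1 replicate 2 (0.0554). For the estrogen-response list camera gave an adjusted p of 0.0140, and adjusted p = 0.511 with an estimated correlation. The number of estrogen-response genes that fell was 6 without siLuc replicate 1 and 6 without siLuc replicate 2.

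Because the title of the series names splicing, and HP1 alpha was profiled, splicing and chromatin factors were examined. Of 36 tested SR and hnRNP splicing regulators 7 fell and none rose (5 fell adjusted over the list alone), with a median log2 fold change of -0.30 (-0.19 without siLuc replicate 1). SRSF2 fell from 477 ± 0.363 to 312 ± 2.72 CPM (-0.61 ± 0.0713) and the SR protein kinase SRPK1 by 0.78 on the log2 scale. Camera gave an adjusted p of 0.00112, and adjusted p = 0.511 with an estimated correlation; the number that fell was 2 without siLuc replicate 1 and 19 without a filter on low counts. Of 39 core spliceosome genes 7 fell and none rose (13 fell adjusted over the list alone), with SNRPA at -0.88 ± 0.123 and a median of -0.18. The core spliceosome list had a camera adjusted p of 0.0103, and adjusted p = 0.357 with an estimated correlation; the number of core spliceosome genes that fell was 1 without siLuc replicate 1, 2 without siLuc replicate 2, 12 with library totals and 13 without a filter. Of 21 genes of heterochromatin and DNA methylation 8 fell and none rose (10 fell adjusted over the list alone), with a median of -0.37. The histone methyltransferase SUV39H1 fell by 0.81 on the log2 scale, and the chromatin remodeler HELLS by 1.15. CBX5, which encodes HP1 alpha, was at -0.71 (edgeR adjusted p = 0.0283), a call lost without siLuc replicate 2 (adjusted p = 0.155) and without siAGO1 replicate 1 (0.0904). For the heterochromatin list camera gave an adjusted p of 0.00539, and adjusted p = 0.357 with an estimated correlation; 5 fell without siLuc replicate 1 and 4 without siLuc replicate 2.

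The remaining lists called by camera moved upward. Of 21 immediate early genes 9 rose and 3 fell (11 and 3 adjusted over the list alone), among them FOSB at 2.39 ± 0.311 and BTG2, while EGR3 was at -1.03 ± 0.107; camera gave an adjusted p of 0.0442, and adjusted p = 0.604 with an estimated correlation. The number of immediate early genes that rose was 3 without siLuc replicate 1, 3 without siLuc replicate 2 and 5 without siAGO1 replicate 2, when the camera adjusted p was 0.155. Of 60 cytosolic ribosomal protein genes 8 rose and 3 fell (7 and 3 adjusted over the list alone), with RPL13A at -1.01 ± 0.110 against a list median of 0.34 (0.58 without siAGO1 replicate 1 and 0.21 without siAGO1 replicate 2); camera gave an adjusted p of 0.0131, and adjusted p = 0.634 with an estimated correlation. The number that rose was 0 without siLuc replicate 1, 3 without siLuc replicate 2, 17 without siAGO1 replicate 1 and 0 without siAGO1 replicate 2, when the camera adjusted p was 0.281, and 1 fell without either siLuc library. With DESeq2 13 rose, and without a filter 23 rose and 5 fell; pseudogene copies make these counts uncertain. Of 37 nuclear genes of oxidative phosphorylation 2 rose and 1 fell (0 adjusted over the list alone), with a median of 0.35 (0.23 without siAGO1 replicate 2, and 0.17 by limma on log2 RPKM with a pseudocount of 1); camera gave an adjusted p of 0.0418, and adjusted p = 0.511 with an estimated correlation. COX6C and NDUFA4, which rose, lay at 2.30 ± 0.570 and 1.58 ± 0.0538 CPM in siLuc. COX6C lost its edgeR call without siLuc replicate 2 (adjusted p = 0.128) and without siAGO1 replicate 2 (0.132), and NDUFA4 without each library in turn (0.142 and 0.154 without siLuc replicates 1 and 2, 0.0860 and 0.127 without siAGO1 replicates 1 and 2). UQCRFS1, which fell, lost its call without siLuc replicate 1 (0.155), siLuc replicate 2 (0.0767) and siAGO1 replicate 2 (0.0611). The number of these genes that rose was 1 without siLuc replicate 1, 0 without siLuc replicate 2, 5 without siAGO1 replicate 1, 0 without siAGO1 replicate 2 and 6 without a filter, and this camera call was lost without siLuc replicate 2 (adjusted p = 0.134) and without siAGO1 replicate 1 (adjusted p = 0.0646). Of 31 lists tested, camera with the preset correlation called 15, of which 7 were up and 8 down, and with a correlation estimated from the 4 libraries it called 0. That second form also rests on the few residual degrees of freedom of the 4 libraries. The estimated correlation was -0.0172 for the G1/S list and -0.00306 for p53 targets, below the preset 0.01, and 0.861 for the interferon list. For the G1/S and p53 lists the lost call therefore does not come from correlation between genes.

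**Figure D3:**
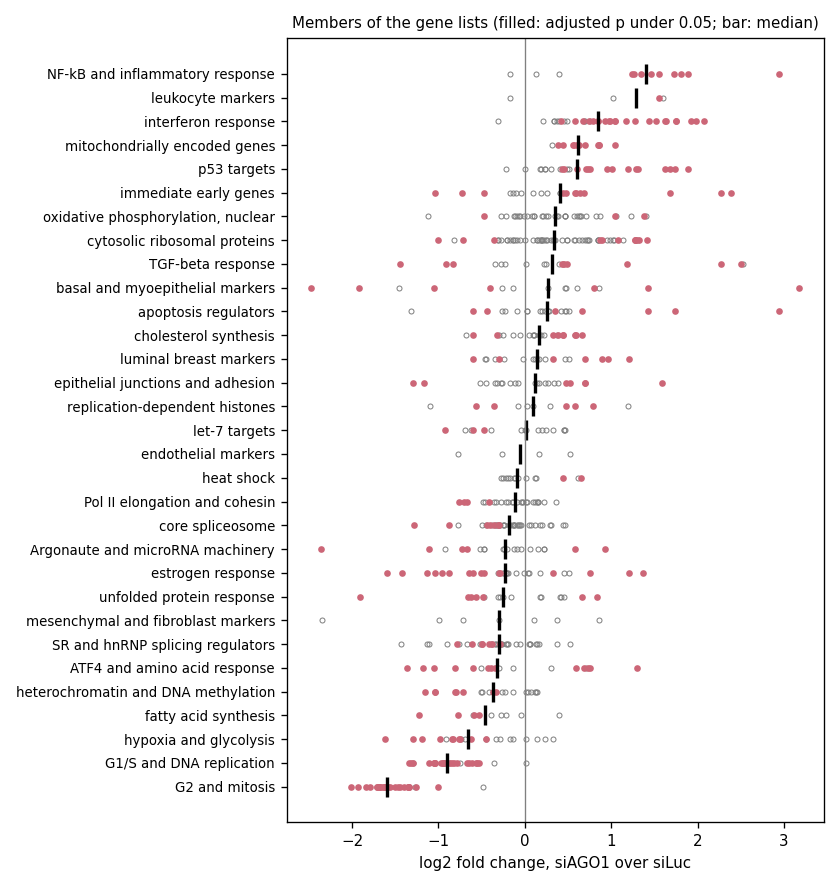
Log2 fold change (siAGO1 over siLuc, x axis) of each tested member of the 31 tested gene lists; filled points passed the test over all genes, open points did not, and black bars are list medians. G2 and mitosis genes lie farthest left, with a median of -1.60, and NF-kB genes farthest right, with a median of 1.40.

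The authors' deposited table of changed genes was set beside these results. Both of its parts fit a fold change of siLuc over siAGO1, the opposite of the parts' names: of 813 genes in the part named as down in siLuc, 809 had higher CPM in siLuc, and all 461 in the part named as up in siLuc had higher CPM in siAGO1. AGO1 stands in the first part with a log2 value of 2.35 in the authors' deposited table. Of 728 tested genes from the first part, 373 (51.2%) were called by edgeR, all lower in siAGO1, and of 347 tested genes from the other part, 311 (89.6%) were called, all higher in siAGO1. TAGLN, FOXI1 and PSCA, with the smallest p-values of the other part in the authors' deposited table, were called here. C3orf14, PPA1 and ECT2 had the smallest p-values of the first part, and none was called here. C3orf14 was at 84.6 and 7.17 CPM in siLuc replicates 1 and 2 and at 10.7 and 2.43 CPM in siAGO1 replicates 1 and 2 (edgeR adjusted p = 0.143). PPA1 was at 39.8 and 1.05 CPM in siLuc and at 1.94 and 1.55 CPM in siAGO1 (edgeR adjusted p = 0.132). ECT2 was at 29.5 and 1.34 CPM in siLuc and at 1.04 and 0.994 CPM in siAGO1 (edgeR adjusted p = 0.0884). In each of these genes siLuc replicate 2 lay near the siAGO1 libraries, so the size of the fall rests on siLuc replicate 1. With all libraries the log2 fold changes were -2.75 for C3orf14, -3.52 for PPA1 and -3.90 for ECT2. They were -3.62, -4.47 and -4.83 without siLuc replicate 2, the library nearest to siAGO1. Without a filter on low counts they were -2.76, -3.53 and -3.91, and the genes were called (edgeR adjusted p = 1.02e-13, 1.14e-13 and 1.77e-15). The log2 values hardly moved, so these calls rest on a different estimate of the spread, not on the counts of these genes. Across the tested genes of each part, which are not independent replicates, the log2 values of the authors' deposited table had a Pearson correlation of -0.484 (Spearman -0.414) in the first part and -0.773 (Spearman -0.838) in the other with the values computed here, the sign being negative because the directions are opposite.

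To describe where AGO1 was found on chromatin, the regions kept by the authors were compared between sets. The positions fit the NCBI36 (hg18) human assembly, which the ChIP files do not name; on chromosome 19 they run to 63789872, past the last gene end on that chromosome in GRCh38. In MCF-7, the Millipore antibody gave 24685 regions covering 11.2 Mb and 4B8 gave 14205 regions covering 26.0 Mb. In MCF10A, 4B8 gave 25097 regions covering 34.9 Mb. HP1 alpha gave 59340 regions in MCF-7 and 45830 in MCF10A, RNAPII 36580 and 5metC 81142 in MCF10A. AGO1 regions of MCF-7 were densest per Mb on chromosomes 20 and 17, which held 24.1% of the Millipore regions and 17.4% of the 4B8 regions, against 4.73% of the 4B8 regions of MCF10A. Chromosomes 1, 8 and 3 held 12.6%, 10.6% and 9.45% of the 4B8 regions of MCF-7, at 7.24, 10.3 and 6.73 regions per Mb. Of the HP1 alpha regions, chromosomes 17 and 20 held 9.23% in MCF-7 and 4.02% in MCF10A. The highest 4B8 signal in MCF-7, by the authors' value, was 158 overlapping reads at chromosome 20, 48720255 to 48788161, followed by 133 at chromosome 17, 57155129 to 57156295, and 117 at chromosome 20, 52164501 to 52193657. The highest Millipore value, 115 in the authors' scaled unit, lay at chromosome 17, 57293869 to 57296064, followed by 59.6 at chromosome 1, 91625212 to 91625799, and 59.1 at chromosome 17, 54538536 to 54539362. In MCF10A the 3 highest 4B8 regions, at 21, 20 and 20 overlapping reads, lay on chromosome 13, from 61478650 to 61482223, 61494061 to 61495371 and 61539529 to 61541150. The highest HP1 alpha region lay at chromosome 7, 158080506 to 158081106, in MCF-7 (1275 overlapping reads) and at chromosome 16, 30875998 to 30876893, in MCF10A (18 overlapping reads). The next highest of MCF-7 had 229 overlapping reads. A 5metC region of MCF10A, at chromosome 7, 158079137 to 158080976, overlapped the MCF-7 one with 758 overlapping reads. High coverage there was therefore not particular to HP1 alpha or to MCF-7. The highest RNAPII region lay at chromosome 11, 62365175 to 62367324, and the highest 5metC region at chromosome 6, 119599997 to 119600565. No annotation of this assembly was used here, so the genes and gene parts at these positions are not given.

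**Figure D4:**
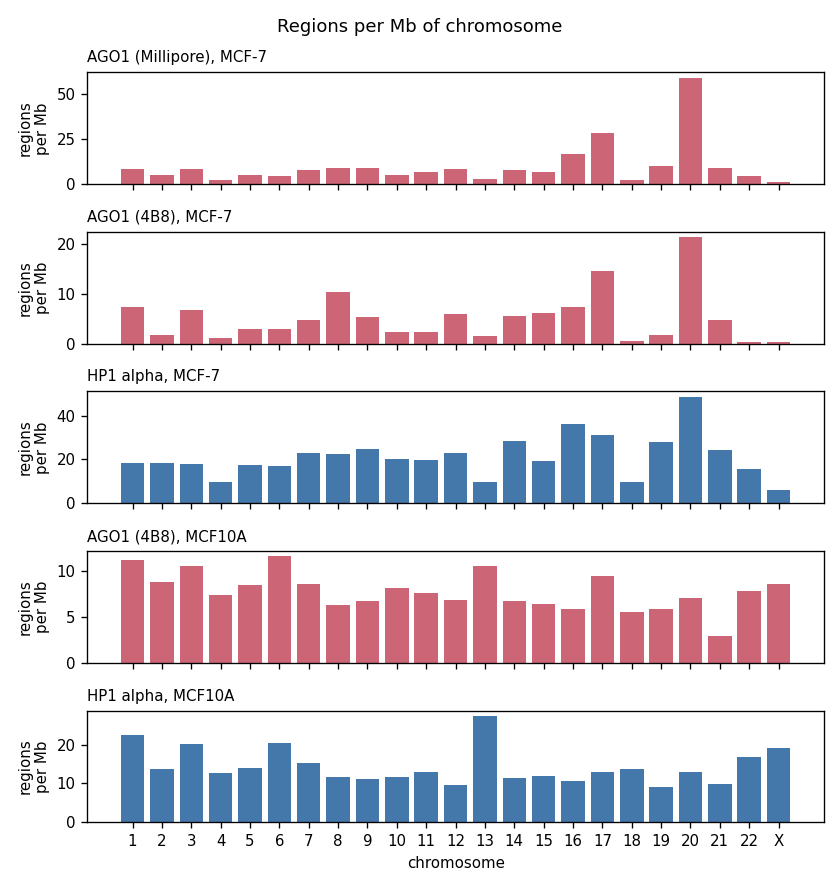
Regions per Mb (y axis, scaled per panel) on chromosomes 1 to 22 and X for AGO1 and HP1 alpha in MCF-7 and MCF10A; bars are single libraries. On chromosome 20 the Millipore set reaches 59.2 and the 4B8 set of MCF-7 21.3 regions per Mb, against 7.05 for 4B8 in MCF10A.

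The 2 AGO1 antibodies were compared in MCF-7. Of the 4B8 regions, 15.1% (2150 of 14205; 95% Wilson interval 14.6 to 15.7) overlapped a Millipore region by at least 1 bp, against a mean of 2.79% (1.36 to 5.10) over 100 circular shifts of the regions within their chromosomes, a ratio of 5.43. Of the Millipore regions 20.7% overlapped a 4B8 region, a ratio of 8.50. With shifts of only 20 to 200 kb, which keep regions within their local neighbourhood, the mean was 10.7% (10.2 to 11.3) and the ratio for 4B8 regions was 1.41.

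AGO1 regions were then compared between the lines. Of the 4B8 regions of MCF-7, 3.49% (496 of 14205; 95% Wilson interval 3.20 to 3.81) overlapped a 4B8 region of MCF10A, against 2.68% (2.21 to 3.26) over the circular shifts, a ratio of 1.31. The overlap no longer exceeded every random placement when the regions were placed on those of the other sets (ratio 1.03) or when the higher-scoring part of each set was used (ratio 1.37). Of the HP1 alpha regions of MCF-7, 2.97% (1763 of 59340; interval 2.84 to 3.11) overlapped one of MCF10A, against 1.82% (1.61 to 2.07), a ratio of 1.63. Placed on the regions of the other sets, the HP1 alpha ratio was 0.821, below all random placements.

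Co-occurrence of AGO1 with HP1 alpha was examined in each line. In MCF-7, 12.6% of the 4B8 regions (1793 of 14205; 95% Wilson interval 12.1 to 13.2) overlapped an HP1 alpha region, against 5.64% (3.84 to 7.96) over the circular shifts, a ratio of 2.24. In MCF10A, 4.51% (1131 of 25097; interval 4.26 to 4.77) did, against 3.32% (2.92 to 3.90), a ratio of 1.36. Placed on regions of the other sets, the ratios were 0.813 in MCF-7 and 0.758 in MCF10A, and with local shifts the ratio was 1.19 in MCF-7, above all 100 shifts, and 1.05 in MCF10A, within their range. Of the Millipore regions of MCF-7, a comparison added after seeing the data, 14.7% (3631 of 24685; interval 14.3 to 15.2) overlapped an HP1 alpha region, against 2.88% (1.87 to 4.37) over the circular shifts, a ratio of 5.11. That ratio was 2.05 with local shifts and 1.55 placed on regions of the other sets, above all random placements in both. The difference between the lines was not tested.

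In MCF10A, 5.39% of the 4B8 regions (1353 of 25097; 95% Wilson interval 5.12 to 5.68) overlapped an RNAPII region, against 3.6% (3.10 to 4.15) over the circular shifts, a ratio of 1.5, and 9.83% (2467; interval 9.47 to 10.2) overlapped a 5metC region, against 7.45% (6.56 to 8.28), a ratio of 1.32. HP1 alpha regions of MCF10A overlapped RNAPII more often, at 10.6% (4847 of 45830; interval 10.3 to 10.9) against 2.83% (2.38 to 3.41), a ratio of 3.74. Placed on the regions of the other sets, the 4B8 ratios were 0.630 with RNAPII and 0.545 with 5metC, and that of HP1 alpha with RNAPII was 1.80. With local shifts the 4B8 ratio was 1.07 with RNAPII, above all 100 shifts, and 0.925 with 5metC, below all 100 shifts. That of HP1 alpha with RNAPII was 2.55, above all 100 shifts. Heights in these MCF10A sets reached only 18 (HP1 alpha) and 41 (RNAPII) overlapping reads. The controls without antibody were not analysed here, so background shared by both sets was not examined.

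**Figure D5:**
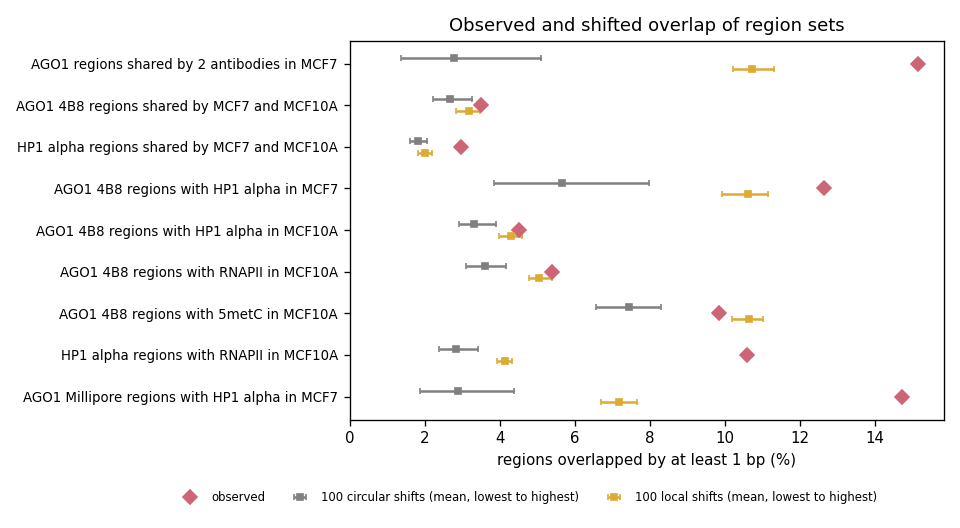
Share of regions (x axis, percent) overlapping the other set by at least 1 bp for pairs of sets; diamonds are observed values, squares with bars the mean and range of 100 circular or 100 local shifts. The AGO1 antibodies overlap at 15.1%, above both kinds of shift, while 4B8 with 5metC at 9.83% lies above the circular and below the local shifts.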

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

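Shifts of 20 to 200 kb and leaving out chromosomes 17 and 20 were chosen after seeing the data, as were the alternatives for the authors' deposited table and the comparison of Millipore regions with HP1 alpha; the other alternatives were chosen before the data were examined. The fall of AGO1 kept its direction and its call under all 12 alternatives, with log2 values from -2.46 to -1.91. The count of 3468 changed genes became 1102 with a log2 fold change of at least 1, and 1601 to 2896 when 1 library was left out (1723 without siLuc replicate 1, 1601 without siLuc replicate 2), where fewer samples entered the fit. DESeq2 called 3574, RLE factors 3474, library totals 3537 and a CPM of at least 1 3478. Limma on RPKM called 3048 and 3038 with pseudocounts of 0.1 and 1. Without a filter 5011 of 20972 genes were called. For C3orf14, PPA1 and ECT2 the adjusted p fell there at almost the same log2 fold change, so that fit took their spread to be smaller. With the replicate number as a block 5094 were called, including all 3468, and also C3orf14, PPA1 and ECT2 (edgeR adjusted p = 5.57e-08, 0.00188 and 0.000149). Under this block 18 SR and hnRNP genes fell and 1 rose, 14 core spliceosome genes fell and 2 rose, and 21 ribosomal protein genes rose and 5 fell. The camera call for oxidative phosphorylation was lost there (adjusted p = 0.0601). Deviations of same-numbered libraries correlated at 0.0930 over all tested genes and at 0.234 over genes with a mean of at least 5 CPM, but with only 2 pairs and no label of a shared batch the numbers were not taken to pair the samples. The camera calls went from 15 to 0 with an estimated correlation, which also leaves the test few degrees of freedom, and lay between 14 and 18 otherwise. In all, 684 genes of the authors' deposited table were called, and 572 to 989 under the alternatives. Over 111 other named genes, 1261 values kept their direction and their side of the threshold, 51 lost the call, 12 gained it and 8 changed sign without a call (in STAT1, MDM2 and PPA1).

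For regions, random placement on the regions of the other sets gave a ratio of 0.821 for HP1 alpha between lines. It gave 0.813 and 0.758 for 4B8 with HP1 alpha in MCF-7 and MCF10A, 0.630 with RNAPII and 0.545 with 5metC. For 4B8 between lines the overlap lay within these placements (1.03). Such placements carry the overlap of the other sets, so a ratio under 1 is not an overlap below chance. Of the RNAPII regions, 12.9% overlapped HP1 alpha of MCF10A, against 2.97% of the HP1 alpha regions of MCF-7. What each other set contributed was not tested. The higher-scoring part of each set also left 4B8 between lines within chance (1.37). Local shifts gave 1.05, within chance, for 4B8 with HP1 alpha in MCF10A and 0.925, below chance, for 4B8 with 5metC. The overlap of the AGO1 antibodies stayed above all random placements in each alternative, with ratios from 1.41 to 8.84. So did HP1 alpha with RNAPII, with ratios from 1.80 to 4.54, and Millipore regions with HP1 alpha in MCF-7, with ratios from 1.55 to 7.45. Millipore regions also lay above local shifts with RNAPII of MCF10A (ratio 1.74), so such an excess is not particular to the AGO1 antibodies. Genes at AGO1 regions, and changed genes near them, were not run for want of an annotation of the build used here. In the simulated counts, changes of a log2 of 1 were recovered for 40% of genes below a mean of 20.2 CPM and 92% of those above it, 66% overall. These shares do not measure how complete the calls in the data are.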

Other observations

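Of the tests reported here, those of replicate order in the genes not called, of their change after knockdown, of the crowded windows, of local shifts for the antibodies and of where the tallest regions lie were chosen only after the result was seen; the gene lists were fixed before the data were examined.

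Several gene lists were not called by camera. Among 20 genes of the Argonaute and microRNA machinery, 4 fell and 2 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.110). The microRNA precursor exporter XPO5 fell from 103 ± 5.53 to 47.8 ± 2.37 CPM (log2 fold change -1.11 ± 0.0925) and the RNA helicase MOV10 rose from 31.4 ± 1.11 to 59.8 ± 7.89 CPM; the number that rose was 1 without siLuc replicate 1. Of 16 let-7 targets none rose and 3 fell (3 adjusted over the list alone), among them HMGA1 at -0.60 ± 0.0757 and CDC25A at -0.92 ± 0.131, with a list median of 0.01 (-0.05 without siLuc replicate 2 and 0.21 without siLuc replicate 1) but a mean of -0.09 and a downward camera direction (adjusted p = 0.746). Of 26 genes of Pol II elongation and cohesin, 4 fell and none rose (4 adjusted over the list alone; 2 rose without siAGO1 replicate 1): SMC1A at -0.70 ± 0.0747, the FACT subunits SUPT16H at -0.67 ± 0.0757 and SSRP1 at -0.77 ± 0.0940, and NELFCD at -0.41, whose edgeR call was lost without siLuc replicate 1 (adjusted p = 0.0837) and without siLuc replicate 2 (0.140); the list had a camera adjusted p of 0.134.

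Basal and luminal markers moved both ways. Of 15 tested basal and myoepithelial markers, TP63, KRT6A (-1.91 ± 0.199), CD44 (-1.05) and SFN (-0.40) fell, and ACTA2 (3.18), CAV1 (1.42 ± 0.168) and CAV2 (0.80) rose (5 fell and 5 rose adjusted over the list alone; camera adjusted p = 0.972). ACTA2 lay at 0.416 ± 0.240 CPM in siLuc; the edgeR call for SFN was lost without siLuc replicate 1 (adjusted p = 0.0536) and siLuc replicate 2 (0.162), and that for CAV2 without siLuc replicate 1 (0.106), siLuc replicate 2 (0.111) and siAGO1 replicate 1 (0.0735). Of 19 luminal markers 5 rose and 2 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.159), with ELF3 at 0.96 ± 0.102, CLDN4 at 0.69 ± 0.0843 and SPDEF at -0.59 ± 0.0713; the number that fell was 1 without siLuc replicate 1. Of 23 genes of epithelial junctions 5 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.488), the falls being beta-catenin CTNNB1, from 105 ± 2.98 to 42.6 ± 4.07 CPM, and PKP2 at -1.16 ± 0.156; 2 rose without siLuc replicate 1 and 3 without siLuc replicate 2. Markers of other cell types were low, and 7 of 18 mesenchymal, 4 of 9 endothelial and 4 of 15 leukocyte markers passed the filter and were tested. No mesenchymal or endothelial marker passed (0 adjusted over the list alone, camera adjusted p = 0.541 and 0.972). COL1A1 had an edgeR adjusted p of 0.0565, and 0.0135 without a filter, and ESAM one of 0.238. The leukocyte markers had a median log2 fold change of 1.29 (camera adjusted p = 0.258). Of these ITGAM rose (1 adjusted over the list alone), at 2.21 ± 0.237 CPM in siAGO1. Its call was lost without any 1 library, at log2 fold changes from 1.23 to 1.94.

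Stress and biosynthesis lists were split. Of 18 TGF-beta response genes 6 rose and 3 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.159), with ID3 at 1.18 ± 0.0871 and the receptor TGFBR1 at -1.45 ± 0.166; 3 rose without siLuc replicate 1. Of 22 apoptosis regulators 5 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.0636), with the p53-inducible BBC3 at 1.74 ± 0.166, BIK at 1.43 ± 0.198 and BCL2L1 at 0.66 ± 0.0762. For this list 0 fell without siLuc replicate 1 and 0 without siLuc replicate 2, and 1 fell without either siAGO1 library; camera called it without siLuc replicate 1 (adjusted p = 0.0229) and without siAGO1 replicate 2 (adjusted p = 0.0171). Of 17 unfolded protein response genes 5 fell and 2 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.258), PDIA6 falling from 152 ± 6.10 to 40.4 ± 6.66 CPM and EDEM1 being at 0.83 ± 0.0814; 1 rose without siLuc replicate 1 and 1 without siLuc replicate 2, when 3 fell. Of 18 ATF4 and amino acid response genes 8 fell and 5 rose (8 and 5 adjusted over the list alone; camera adjusted p = 0.258), with SHMT2 at -1.18 ± 0.110, PHGDH at -1.36 ± 0.135 and STC2 at 0.76 ± 0.0761; without either siLuc library 5 fell and 3 rose, and 3 rose without either siAGO1 library. Of 23 cholesterol synthesis genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.137), with EBP at -0.60 ± 0.0771; the number that rose was 2 without siLuc replicate 1, 0 without siLuc replicate 2 and 4 without siAGO1 replicate 1, and 1 fell without either siLuc library. Of 11 histone genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.334), with H2BC21 at 0.79 ± 0.0810; 0 fell without siLuc replicate 1 or without siAGO1 replicate 1 and 1 without siLuc replicate 2 or without siAGO1 replicate 2. Of 14 heat shock genes BAG3 (0.65 ± 0.0773) and DNAJA1 rose (2 adjusted over the list alone; camera adjusted p = 0.972), DNAJA1 with an edgeR adjusted p of 0.0211 that became 0.0808 without siLuc replicate 1 and 0.130 without siLuc replicate 2; 3 heat shock genes fell without siAGO1 replicate 1. The heat shock median was -0.09 (-0.05 without siLuc replicate 2 and -0.03 without siAGO1 replicate 2), while its mean of 0.04 and the camera direction were upward. Without a filter on low counts camera called the lists of Argonaute machinery (adjusted p = 0.0403), Pol II elongation (0.0441) and apoptosis regulators (0.0465); 7 Argonaute machinery, 5 luminal, 3 mesenchymal, 5 TGF-beta, 4 apoptosis and 4 cholesterol genes fell, 4 unfolded protein response genes rose, and 8 epithelial junction genes rose and 4 fell.

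A pattern to follow up is the 355 genes that the authors' deposited table places lower in siAGO1 and that edgeR did not call. In these genes replicate 1 stood above replicate 2 in both arms, by a median log2 of 0.934 in siLuc and 0.802 in siAGO1, against 0.03 and 0.20 in the 373 genes called. A wide spread between replicates keeps a gene from being called, so the size of this gap is in part set by how the 355 genes were chosen. Genes next to them, outside the set, had a siLuc median of 0.0665, above the highest of 1000 random gene sets (0.0377), so a bias shared by neighbours, such as base composition, may enter, although it is small beside 0.934; base composition itself was not measured. A fall after AGO1 knockdown stays open, since the set was selected for that direction. The median log2 of siAGO1 over siLuc was -0.748 for libraries numbered 1 and -0.702 for those numbered 2. Set against a single siLuc library, siAGO1 stood 1.16 below replicate 1 and 0.263 below replicate 2, values that also carry the gap between the siLuc replicates.

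AGO1 regions of MCF-7 crowd on chromosomes 17 and 20. The 31 of 3091 windows of 1 Mb with the most 4B8 regions of MCF-7 held 22.5% of the 4B8 and 20.5% of the Millipore regions of MCF-7; 14 of them lie on these chromosomes and 17, the densest included, on chromosomes 1, 3, 8 and 15. A candidate explanation is a higher DNA copy number, MCF-7 being known to carry amplified segments on both. The share of HP1 alpha regions in MCF-7 over MCF10A was 2.93 across all 31 windows. It was 7.18 in those on chromosome 20, 5.32 on 15, 2.97 on 8, 2.56 on 17, 1.90 on 1 and 0.691 on 3. A window of chromosome 20 with 168 4B8 regions held 9 HP1 alpha regions in each line. Copy number was not measured here on any chromosome, so windows off chromosomes 17 and 20 do not count against this explanation or for it. For 4B8 the factor was 16.9, but the windows were chosen by these regions, and with 1 library per set denser AGO1 binding cannot be told apart from a stronger effect of copy number on that library. Crowding that is even over the 20 to 200 kb of the local shifts did not by itself give the overlap of the antibodies. At 15.1% that overlap lay above the highest of 100 local shifts (11.3%), and was 1.41 times their mean. Crowding finer than 20 kb is broken by every shift, so it cannot be excluded as the source. Millipore regions also exceeded such shifts with RNAPII of MCF10A, at a ratio of 1.74.

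The 4B8 regions of MCF-7 and MCF10A rarely coincided. Low read depth could hide shared regions; among the tallest regions (2841 of the 14205 in MCF-7 and the same share in MCF10A) 22 overlapped, 1.14 times the mean of 100 local shifts and within their range. This does not decide, because height may follow the copy number of each line: 55.5% of the tallest MCF-7 regions lie in the 31 crowded windows, against 22.5% of all its 4B8 regions. Low depth and a difference between the lines therefore cannot be told apart, with 1 library for each.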
